A study of Homo sapiens with 6 samples.

How the data were processed

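BG4 ChIP-seq was performed on U2OS cells, untreated or treated with 1,6-hexanediol, with 2 ChIP libraries and 1 input library per condition. Per the labels, chromatin was fixed with formaldehyde at 1% for 10 min, the reaction was stopped with glycine at 0.125 M, and chromatin was sheared by sonication. No molecular identifiers are named. The dose and duration of hexanediol are not given in the sources used here. The submitters' processing notes name FastQC 0.11.9, Bowtie2 2.5.0, SAMtools and MACS2 2.2.7.1 and the build hg38. Settings, duplicate removal and the pairing of reads are not given in the sources used here.

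The authors deposited 1 MACS2 peak list per condition, which the labels tie to both ChIP libraries of that condition. Input files were not analysed here. Each peak has a position, a fold enrichment over the caller's local background (a ratio deposited by the authors), −log10 p and −log10 q as deposited by the authors, and a summit position. The deposited lists were kept by the authors at a q-value of 0.05, since the lowest −log10 q was 1.31 in the Ctrl list and 1.30 in the HD list. Fold and −log10 q themselves were used to describe, rank or filter peaks within their own list, since the authors made each list separately. Values were compared across lists as the fragment numbers and depths recovered from fold and p. No value per library was used here, so the spread between libraries is unknown and no difference between conditions was tested against it. Tests between the 2 lists take peaks or genes as their units. All peak names of the HD list contain the number of replicate 1, so the list may not rest on both libraries.

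The caller's fold and p-value were used together to recover the number of ChIP fragments over each summit and the caller's expectation from input, a step chosen after seeing the data. MACS2 computes the fold as (pileup + 1) / (expectation + 1) and p as the upper Poisson tail of the pileup, where the pileup is a whole number of fragments multiplied by a scale. The expectation is on this scaled pileup, so it was divided by the scale wherever it was set against fragment numbers. The scale (0.927 for Ctrl, 0.715 for HD) and the genome-wide expectation (3.46 and 3.94) were found from repeated pairs of fold and p. A whole number of fragments matched the deposited −log10 p within 0.01 for 3506 of 3507 Ctrl peaks and for all 2269 HD peaks, and 3.31% and 4.19% of peaks had more than 1 such number, of which the closest was taken. The steps of the expectation put the caller's fragment length at 191 bp in Ctrl and 200 bp in HD. These steps fitted 47.3% and 44.9% of the local expectations under 20 that were not whole numbers. Whether the caller extended single reads or used read pairs is not given in the sources used here. Depth per Mb refers to the genome size given to the caller. The HD to Ctrl ratio was 1.40 for ChIP depth, 1.08 for input depth and 1.14 for the genome-wide expectation. Poisson intervals on fragment numbers cover counting error only, since amplified reads are not independent molecules.

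Gene positions came from a RefSeq gene table of GRCh38.p14, the same assembly as hg38, with 59792 genes. Genes on scaffolds or without a place, 798 in all, were left out, which left 19817 protein-coding genes on chromosomes 1 to 22 and X. The table holds no strand, transcript or sequence, so the planned window around transcription start sites became a window of 1 kb either side of both gene ends, and the planned G4 motif and GC content measurements were not made. The model of retention accordingly had the terms log2 fold, gene-end location and log2 width, each standardised. Comparisons used peaks on chromosomes 1 to 22 and X. Peaks on other sequences were left out of them, 131 in Ctrl and 97 in HD. Peaks overlapped when they shared at least 1 bp. Random placements kept each peak's width and chromosome (100 placements). Trends over quintiles of fold were tested with 100000 permutations, and shares were compared with two-sided Fisher's exact tests.

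Lists of genes, 11 in all (G4 oncogene promoters, cytosolic ribosomal proteins, replication-dependent histones, immediate-early and heat shock, G4 helicases and binding proteins, condensate and nuclear body proteins, cell cycle and replication, mesenchymal and osteosarcoma line genes, tissue-restricted genes, small structural RNA genes and numbered zinc finger genes), were fixed before the data were examined, and all their members were matched to the table. Their members, coding or not, were compared with all other protein-coding genes. The Benjamini-Hochberg adjustment was made over the 22 tests of marked genes and, separately, over the lists for lost genes and over those for the difference between lists. The genes named in the text were the 10 Ctrl-only genes with the highest −log10 q, the 10 genes in both lists with the best summed rank, the 10 HD-only genes with the highest −log10 q, with 1 gene per peak, and up to 4 marked members of each list by −log10 q. A gene that this rule names is not reported here. Alternatives were a stricter −log10 q of 3, equal list lengths, other overlap rules, merged or main-chromosome peaks, windows of 500 bp and 2 kb, all gene types and stratification by fold, and, chosen after seeing the data, a fold of at least 2, leaving out the ribosomal DNA span and 1 gene per peak.

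The calculations were tested on simulated data. In simulated lists of 3376 and 2172 peaks, 99.6% of overlap calls equalled the truth, an odds ratio of 1.73 for gene-end location was found as 1.70, and 5.5% of 200 shuffled draws gave a trend p under 0.05. Fragment numbers were recovered exactly for 100% of 3507 simulated Ctrl peaks and 2269 simulated HD peaks with a single solution. These simulated values were built with the same formula that the recovery inverts. They test the calculation and not whether the deposited values follow that formula. Simulated lists of 40 genes marked at 4 times the odds of the 19817 genes were called at a raw p under 0.05 in 95.5% of 200 draws, and lists with no difference in 1% of draws. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used.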

Results

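DNA G-quadruplexes (G4s) are stacked structures that guanine-rich single strands can fold into. They were mapped in U2OS cells, a human osteosarcoma line, by chromatin immunoprecipitation and sequencing (ChIP-seq) with BG4, an antibody directed at G4s. The cells were either untreated (Ctrl) or treated with 1,6-hexanediol (HD), an aliphatic alcohol that dissolves many biomolecular condensates. The comparison asks whether the genomic sites recovered with BG4 differ when condensates are disrupted. Each condition had 2 ChIP libraries and 1 input library, 6 libraries in all, and 1 peak list per condition was analysed. No value therefore has a replicate error, and no difference between conditions was tested against the spread between libraries. The p-values below take peaks or genes as their units and describe these 2 lists. All 2269 peak names of the HD list carry the number of replicate 1, and those of the Ctrl list carry no replicate number. Whether the HD list rests on 1 or on both libraries is not given in the sources used here. The fragment numbers recovered from the peak caller's values put the ChIP depth at 19603 fragments per Mb for Ctrl and 27539 fragments per Mb for HD. Intervals on fragment numbers and on shares are exact 95% Poisson and binomial intervals, respectively, and cover counting error only.

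The untreated cells gave more G4 peaks than the hexanediol-treated cells on all 23 chromosomes compared (1 to 22 and X). The Ctrl list held 3507 peaks covering 1153 kb and the HD list held 2269 peaks covering 815 kb, which is 35.3% fewer peaks. Relative to Ctrl, the number of HD peaks was lowest on chromosome 6, with 36 against 73 peaks (49.3%), and highest on chromosome 19, with 156 against 197 peaks (79.2%). Chromosome 17 carried 268 Ctrl and 169 HD peaks, and the X chromosome carried 12 and 8. The peaks were narrow in both lists, with a median width of 265 bp in Ctrl and 274 bp in HD. The authors' fold enrichment over the local background had a median of 4.17 in the Ctrl list and 4.02 in the HD list, and the lowest number of ChIP fragments at a called summit was 15 and 20, respectively. The length of a peak list depends on depth and enrichment, and no count of peaks per library was used here.

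Most of the Ctrl peaks with the highest fold were found again after hexanediol, and most of those with a lower fold were not. Of 3376 Ctrl peaks on chromosomes 1 to 22 and X, 1300 (38.5%, interval 36.9 to 40.2) shared at least 1 bp with an HD peak and 2076 did not. Of 2172 HD peaks, 1296 (59.7%, interval 57.6 to 61.7) overlapped a Ctrl peak and 876 did not. When the peaks of the other list were placed at random on their own chromosomes, a mean of 0.0669% of Ctrl peaks and 0.105% of HD peaks were overlapped over 100 placements. Placement was uniform along each chromosome and took no account of gene ends, where many peaks of both lists lay. It is therefore a low baseline for lists that favour the same kind of site. The share of Ctrl peaks found in the HD list was 29.6% (26.2 to 33.2), 29.2% and 31.0% in the lowest 3 quintiles of fold enrichment, 44.7% in the next and 58.0% (54.2 to 61.7) in the highest, a difference of 28.4 percentage points between the ends. The share of HD peaks found in the Ctrl list was 49.1% (44.3 to 53.9) in the lowest quintile and 80.5% (76.4 to 84.1) in the highest. Both trends had p = 1e-05 in a two-sided permutation test over peaks, the smallest value that 100000 permutations can give. Among the 50 peaks with the highest fold, 41 Ctrl peaks (82.0%, 68.6 to 91.4) lay in the HD list. In the other direction, 47 HD peaks (94.0%, 83.5 to 98.7) lay in the Ctrl list. Among the 50 peaks with the highest −log10 q, these numbers were 42 (84.0%, 70.9 to 92.8) and 49 (98.0%, 89.4 to 99.9). A high −log10 q is not always a high fold. Several HD peaks on chromosome 1 with a very high −log10 q had a high input expectation and lay in the lower quintiles of fold.

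**Figure D1:**
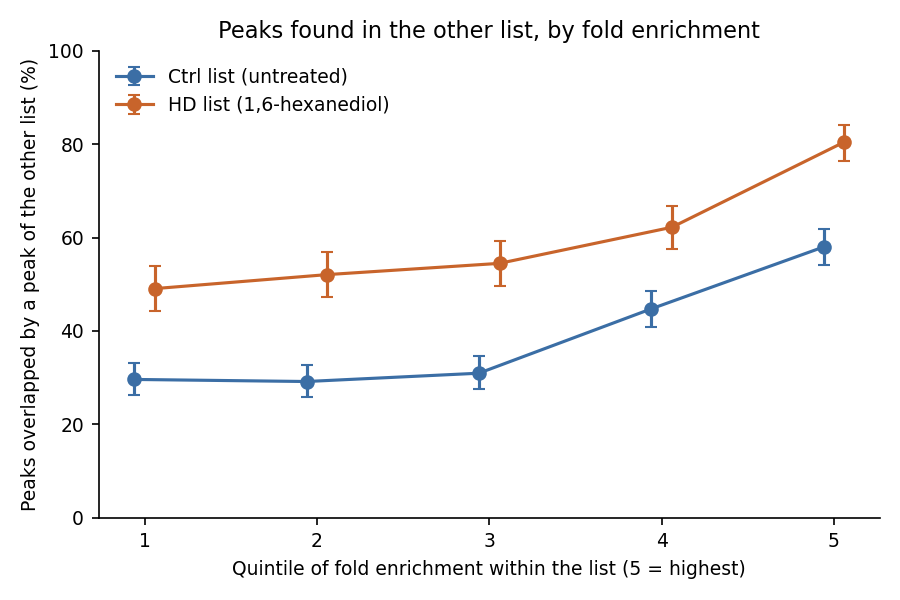
Share of peaks (y axis, percent) overlapped by a peak of the other list, by quintile of the authors' fold enrichment within each list (x axis, 5 is highest), for the Ctrl list (blue) and the HD list (orange). Points are shares of 675 or 676 Ctrl peaks and of 434 or 435 HD peaks, with exact 95% binomial intervals, and the share is 29.6% in the lowest and 58.0% in the highest Ctrl quintile, and 49.1% and 80.5% in HD.

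G4 peaks lay at the ends of protein-coding genes in both conditions, close to the end itself. The annotation used carried no strand, so start and end sites were not told apart and the window was 1 kb either side of either gene end. In the Ctrl list 1811 of 3376 peaks (53.6%, 51.9 to 55.3) and in the HD list 1318 of 2172 peaks (60.7%, 58.6 to 62.7) touched such a window, against means of 3.32% and 3.43% for randomly placed peaks. The summit was within 250 bp of the gene end for 78.6% of the gene-end peaks in Ctrl and 77.2% in HD. Of the marked genes at least 10 kb long, 17 of 1722 (0.987%) in Ctrl and 11 of 1260 (0.873%) in HD carried peaks at both ends. Another 548 Ctrl peaks (16.2%) and 280 HD peaks (12.9%) lay within genes away from their ends.

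Ctrl peaks at gene ends were found again more often than Ctrl peaks elsewhere. The share found in the HD list was 46.3% (44.0 to 48.7) at gene ends, 28.8% (25.1 to 32.8) within genes away from their ends, and 29.8% (27.0 to 32.7) outside genes. Gene-end location was correspondingly more frequent among shared than among Ctrl-only peaks (64.5% against 46.8%, odds ratio 2.07, two-sided Fisher's exact test, p = 7.73e-24) and among shared than among HD-only peaks (64.9% against 54.5%, odds ratio 1.55, p = 1.29e-06 by the same test). In a logistic model of 3376 Ctrl peaks, the odds ratio of being found in the HD list was 1.40 per SD of gene-end location (95% interval 1.29 to 1.53), 1.20 per SD of log2 fold (1.11 to 1.31) and 2.32 per SD of log2 peak width (2.11 to 2.54). The whole HD list had a higher gene-end share than the whole Ctrl list (odds ratio 1.33, Fisher's exact test, p = 2.47e-07). That difference was lost when the same number of peaks, 2172, was taken from each list by −log10 q, where the shares were 60.7% in HD and 59.7% in Ctrl (odds ratio 1.04, Fisher's exact test, p = 0.515).

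Counted by gene, 2160 of 19817 protein-coding genes (10.9%) were marked by a Ctrl peak and 1608 (8.11%) by an HD peak. Both lists marked 1030 genes, where independent lists of these sizes would share 175. The Ctrl list alone marked 1130 genes and the HD list alone 578. By summed rank of −log10 q, the top genes of both lists included ATAD2, a bromodomain ATPase, and KPNB1, the nuclear import receptor importin beta. They also included PPM1D, a phosphatase that acts in the p53 response, and AFG3L2, a protease of the inner mitochondrial membrane. A high input raises −log10 q at a given fold, so this is not a rank of enrichment. The PPM1D peak in HD had an input expectation of 12, against 3.94 genome-wide. Its fold of 4.69 was below the highest HD quintile. The ATAD2 peak (gene ID 29028, chromosome 8, hg38, 123416270 to 123417178 in the Ctrl list) lay across the upper end of the gene and held 76 ChIP fragments (59.9 to 95.1) in Ctrl, 10.1 times (7.93 to 12.6) the number that input gave on the same scale. In HD it held 96 (77.8 to 117), 7.62 times (6.17 to 9.31) that number, in the deeper HD track. The intervals on these ratios, and on those at ribosomal DNA, take the input as known and leave out its counting error. SPATC1L had 73 and 109 fragments, ZNF7 had 71 and 93, and RELL1 had 55 and 68 in Ctrl and HD. STYX had 56 and 87, MAP3K9 had 65 and 74, and MTMR4 had 59 and 68 in Ctrl and HD, respectively. PPM1D had 63 and 84, AFG3L2 had 68 and 83, and KPNB1 had 52 and 56.

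By −log10 q, the strongest genes of the Ctrl list without an HD peak were HGH1, NAT9, OLA1, DMWD, CEP55, TULP3, BLTP2, FAM98A, CIPC and IP6K2. HGH1 (gene ID 51236, Ctrl peak on chromosome 8, 144137539 to 144137832, over the lower end of the gene) had 53 fragments (39.7 to 69.3) against 6.83 from input on the same scale, with the nearest HD peak 9.91 kb away. CEP55, a midbody protein required for the last step of cell division, had 41 fragments (29.4 to 55.6) in a peak on chromosome 10 (93496307 to 93496682), with the nearest HD peak 2065 kb away. The other 8 genes had 37 to 45 fragments. NAT9 had 44, OLA1 had 41 and DMWD had 38. TULP3, a protein of ciliary trafficking, had 44, BLTP2 had 44 and FAM98A had 37. CIPC, a repressor of the circadian factor CLOCK, had 41, and the inositol phosphate kinase gene IP6K2 had 45. By −log10 q, the strongest genes of the HD list without a Ctrl peak were TTLL4, TAF11L3, COQ8A, RPL36AL, MYPOP, NAA10, DCXR, BCLAF1, CRY2 and LOC124902474. TTLL4, a tubulin glutamylase, had 48 fragments (35.4 to 63.6) in a peak on chromosome 2 (218710706 to 218710931) with the nearest Ctrl peak 142 kb away. CRY2, a core repressor of the circadian clock, had 41 fragments (29.4 to 55.6) on chromosome 11 (45847232 to 45847483). COQ8A had 44, RPL36AL had 58 and MYPOP had 42. NAA10, the catalytic subunit of an N-terminal acetyltransferase, had 42, DCXR had 47, BCLAF1 had 41 and LOC124902474 had 50. The summits at NAA10 and TAF11L3 lay outside the gene, 815 bp and 631 bp from its end. TAF11L3 stood apart, with 194 fragments against 82.6 from input on the same scale and a fold of 2.33, 7.98 kb from the nearest Ctrl peak. A missing peak is a missing call, and fragment numbers at uncalled sites were not used here.

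**Figure D2:**
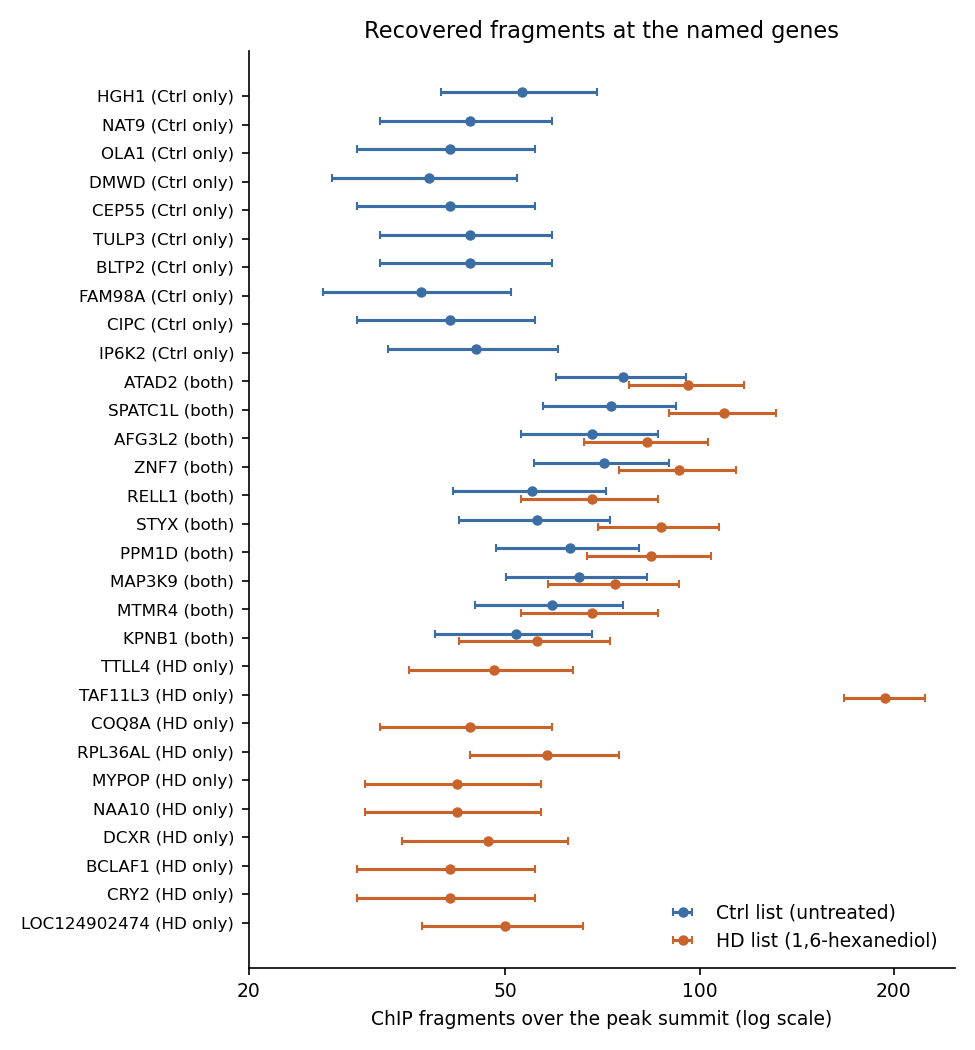
ChIP fragments over the peak summit (x axis, log scale) for the 30 protein-coding genes named by rule (y axis): 10 marked in the Ctrl list only, 10 in both lists and 10 in the HD list only. Points are recovered fragment numbers in Ctrl (blue) and HD (orange), bars are exact 95% Poisson intervals, and no point is drawn where the list has no peak, with ATAD2 at 76 fragments in Ctrl and 96 in the deeper HD track.

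Among the 11 gene lists fixed before the data were examined, genes of condensate and nuclear body proteins, of G4 helicases and G4-binding proteins, and of the cell cycle and replication carried Ctrl peaks more often than other protein-coding genes. For all lists, the other genes were not matched on expression, chromatin state or GC content, so the cause of a difference was not tested. Condensate and nuclear body genes were marked at 11 of 34 members in Ctrl (32.4% against 10.9% of other genes, odds ratio 3.92, two-sided Fisher's exact test, p = 0.000668, adjusted p = 0.0129) and at 7 in HD (20.6% against 8.10%, odds ratio 2.94, adjusted p = 0.0554). SRSF1 and SRSF2, splicing factors of nuclear speckles, and NEAT1, the scaffold RNA of paraspeckles, had 41, 35 and 32 Ctrl fragments and no HD peak. The gene of the nucleolar protein TCOF1 had 37 fragments in each list, but the HD track was 1.40 times as deep, so equal numbers are not equal signal. CAPRIN1, EWSR1, G3BP1 and MED1, 4 of the 7 members marked in HD, were marked in HD only, and these and all HD-only list members given without fragments were named after their values were seen. G4 helicases and binding proteins were marked at 8 of 25 members in Ctrl (32.0%, odds ratio 3.86, exact test, p = 0.00387, adjusted p = 0.0213) and at 4 in HD (16%, odds ratio 2.16, adjusted p = 0.237). BLM and BRIP1, both helicases that unwind G4s, had Ctrl peaks of 28 and 40 fragments and no HD peak, DDX5 and RECQL4 were marked in both lists, and PARP1 in HD only. Cell cycle and replication genes were marked at 13 of 47 members in Ctrl (27.7%, odds ratio 3.14, exact test, p = 0.00118, adjusted p = 0.0129) and at 8 in HD (17%, odds ratio 2.33, adjusted p = 0.116). MCM5, a subunit of the replicative helicase, had 49 and 66 fragments and CDC6, a licensing factor, had 32 and 40, whereas CCNE1 (35 fragments) and MCM10 (25 fragments) were marked in Ctrl only. BUB1, CDC20, ORC6 and RRM2, 4 of the 8 members marked in HD, were marked in HD only. With 2172 peaks from each list, the Ctrl calls of the helicase list (odds ratio 2.95, exact test, adjusted p = 0.105, range over 6 alternatives 0.0162 to 0.105) and of the cell cycle list (odds ratio 2.42, adjusted p = 0.0938, range 0.00226 to 0.0938) were lost. In HD, the condensate list passed with a window of 500 bp (exact test, adjusted p = 0.0408, range 0.0408 to 0.0776) and the cell cycle list at −log10 q of at least 3 (adjusted p = 0.0443, range 0.0443 to 0.511).

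Immediate-early and heat shock genes were the list with the highest marked share in HD. Peaks lay at 9 of 37 members in HD (24.3% against 8.08%, odds ratio 3.65, Fisher's exact test, p = 0.0023, adjusted p = 0.0169) and at 5 in Ctrl (13.5%, odds ratio 1.28, adjusted p = 0.769). JUN, a subunit of the AP-1 factor, BTG2 and HSPA8, a constitutive HSP70, were marked in both lists, with 26 and 33, 27 and 32, and 25 and 29 fragments in Ctrl and HD. The HD track was 1.40 times as deep, so higher numbers there are not higher signal. HSPH1 (21 Ctrl fragments) and HSP90AB1 were marked in Ctrl only, and HSPB1, HSPD1, HSPE1, JUND, KLF10 and SRF in HD only, the last 6 and HSP90AB1 being named after their values were seen. HSPD1 and HSPE1 share a peak, and the HD call was lost when each peak was given to 1 gene (odds ratio 3.16, exact test, adjusted p = 0.081, range over 6 alternatives 0.00226 to 0.081). The difference between the lists did not pass its test over 10 lists (6 HD-only and 2 Ctrl-only members, Fisher's exact test, p = 0.021, adjusted p = 0.21).

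Tissue-restricted genes such as those for albumin, insulin and rhodopsin carried no peak at any of 46 members in either list (upper bound 7.71%), against 10.9% of other genes in Ctrl (Fisher's exact test, p = 0.008, adjusted p = 0.0293) and 8.13% in HD (adjusted p = 0.116). The Ctrl call was lost with equal list lengths (odds ratio 0.126 against 0.0877, exact test, adjusted p = 0.105) and with 1 gene per peak (odds ratio 0.123, adjusted p = 0.109), with a range over 6 alternatives of 0.0222 to 0.109. The replication-dependent histone genes were marked at 2 of 67 members in Ctrl (2.99%, exact test, adjusted p = 0.0839), H2AC19 and H3C15, which shared 1 peak of 17 fragments, and at 0 in HD (upper bound 5.36%, adjusted p = 0.0262). The HD call was lost with 1 gene per peak (odds ratio 0.120 against 0.0835, exact test, adjusted p = 0.0915, range over 6 alternatives 0.0211 to 0.0915). In Ctrl this list passed at −log10 q of at least 3 (exact test, adjusted p = 0.0177) and with a window of 500 bp (adjusted p = 0.0408), with a range of 0.0177 to 0.115. The remaining lists did not pass the test in either condition. G4 oncogene promoters were marked at 2 members in Ctrl and 4 in HD of 22 (exact test, adjusted p = 1 and 0.196), with ABL1 in Ctrl only (27 fragments), and HIF1A (69 fragments), YY1 (29 fragments) and MYC, named after its values were seen, in HD only. Cytosolic ribosomal protein genes were marked at 7 and 4 of 79 (exact test, adjusted p = 0.831 and 0.565), with RPL18 in both lists, RPS19, RPSA and RPL27 among 6 in Ctrl only, and RPL35, RPL8 and RPS13 in HD only. Mesenchymal and osteosarcoma line genes were marked at 7 and 6 of 39 (exact test, adjusted p = 0.299 and 0.237), with MYH9 (34 and 40 fragments, not scaled by depth) among 4 in both lists, TEAD1, ANXA2 and TPM1 in Ctrl only, and COL1A1 and TGFB1 in HD only. Numbered zinc finger genes were marked at 55 and 38 of 509 (exact test, adjusted p = 1 and 0.831), led by ZNF7, ZNF706, ZNF250 and ZNF697, all in both lists. Small structural RNA genes were marked at 2 and 0 of 19 (exact test, adjusted p = 1 and 0.565), RPPH1 (25 fragments) and RN7SL1 (34 fragments) in Ctrl.

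No list passed the test for losing its marked genes more or less often than other genes. Of the Ctrl-marked members, 8 of 11 condensate genes (72.7%), 9 of 13 cell cycle genes (69.2%), 5 of 8 helicase and binding protein genes (62.5%), 6 of 7 ribosomal protein genes (85.7%) and 29 of 55 zinc finger genes (52.7%) had no HD peak. The share over other genes was 52.2% to 52.3%, and the adjusted p-values of the 10 lists with a Ctrl-marked member were between 0.907 and 1 (Fisher's exact test). Nor did the split of a list's members into Ctrl-only and HD-only pass against that of other genes, with adjusted p from 0.21 to 1 over the same 10 lists (exact test). Of these lists, 9 had 2 to 13 Ctrl-marked members, which limits the precision of these comparisons.

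**Figure D3:**
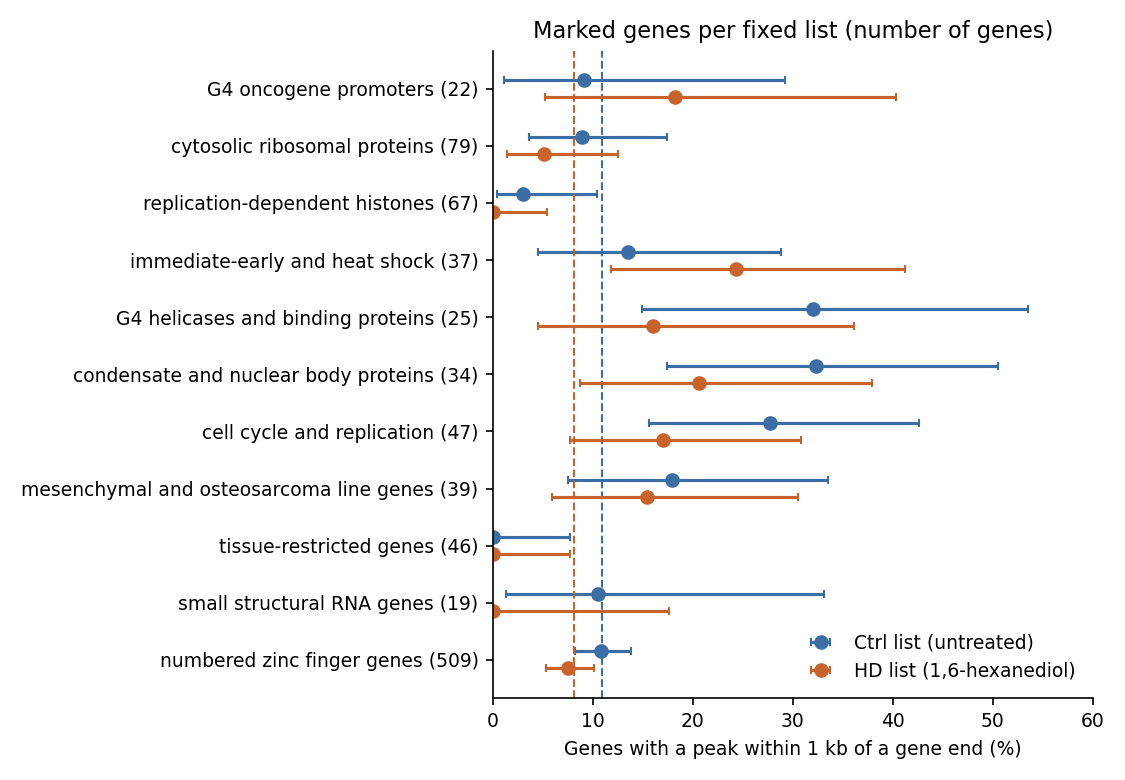
Percentage of genes with a peak within 1 kb of a gene end (x axis) for each of 11 fixed gene lists (y axis, number of genes in parentheses). Points are shares in the Ctrl list (blue) and the HD list (orange) with exact 95% binomial intervals, and dashed lines mark the share of other protein-coding genes, 10.9% in Ctrl and 8.1% in HD, while condensate and nuclear body genes reach 32.4% in Ctrl and 20.6% in HD, and immediate-early and heat shock genes reach 13.5% and 24.3%.

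Ribosomal DNA was densely covered in both conditions. The 3 annotated units of the 45S ribosomal RNA precursor on chromosome 21 were covered by peaks over 80.4% to 89.0% of their length in Ctrl and 83.4% to 96.1% in HD. Strength is ranked here by −log10 q. At RNA45SN2 (8205988 to 8219302) the strongest Ctrl peak held 486 ChIP fragments, 6.26 times (5.71 to 6.84) the number that input gave on the same scale. The strongest HD peak held 610, 6.05 times (5.58 to 6.55) that number. The strongest peaks of RNA45SN3 (8389035 to 8402343) held 457 and 678 fragments (5.36 and 4.85 times), and those of RNA45SN1 (8433222 to 8446572) held 283 and 355 (5.04 and 6.04 times). Around these units, 33 of 41 Ctrl peaks (80.5%, 65.1 to 91.2) were overlapped by HD peaks and 30 of 37 HD peaks (81.1%, 64.8 to 92.0) by Ctrl peaks. Reads from the many ribosomal DNA copies cannot be assigned to a single unit, so the 3 units do not give independent values.

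**Figure D4:**
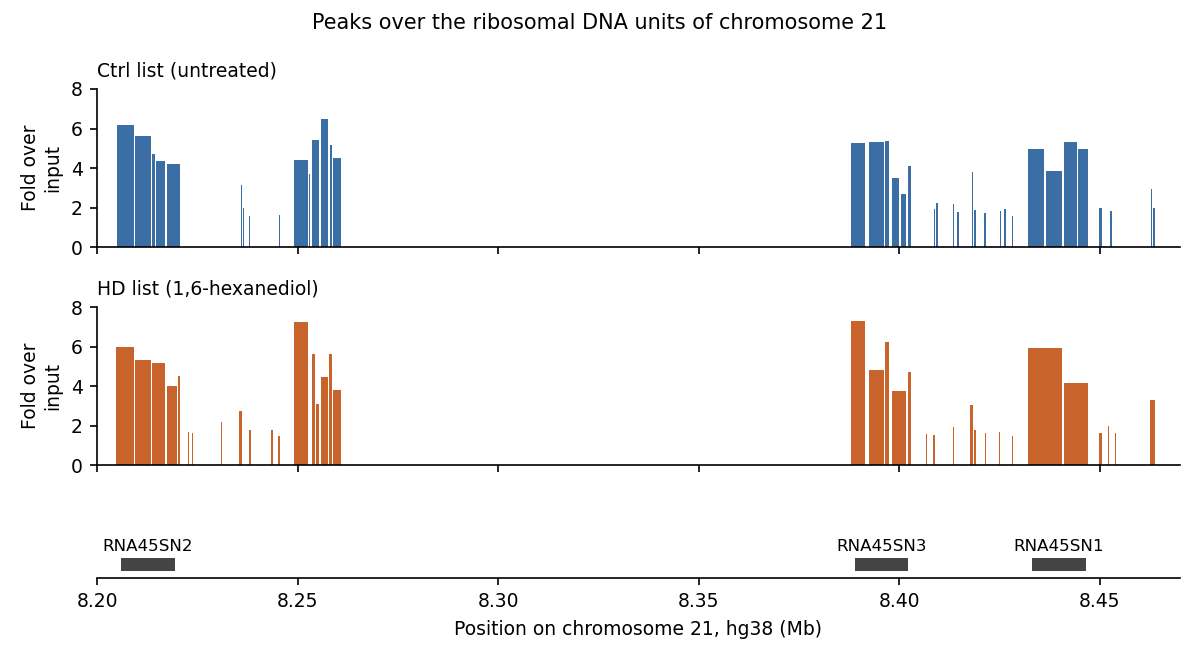
Peaks over the ribosomal DNA of chromosome 21, drawn to scale by position (x axis, hg38, Mb) with the authors' fold over input as height (y axis) for the Ctrl list (blue, 41 peaks) and the HD list (orange, 37 peaks). Grey bars mark the annotated 45S units RNA45SN2, RNA45SN3 and RNA45SN1, covered over 80.4% to 89.0% of their length in Ctrl and 83.4% to 96.1% in HD, and a further covered stretch between RNA45SN2 and RNA45SN3 has no 45S unit in the annotation.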

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

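Among the tests given here, those of depth, of spread between libraries, of copy number and of missing peaks at 1.5 and 2 times the input were chosen only after the result was seen, and the other tests before it. Peaks outside the compared chromosomes stood out because no comparison used them. The mitochondrial genome was covered over 15.4 kb by 5 Ctrl peaks and over 14.5 kb by 6 HD peaks, with folds over input of up to 3.11 in Ctrl and 2.67 in HD. Unplaced and alternate sequences held 118 Ctrl peaks (median fold 2.33) and 86 HD peaks (median fold 2.09), of which 51.7% (42.3 to 61.0) and 64.0% (52.9 to 74.0) were overlapped by a peak of the other list.

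Genes such as HGH1, OLA1 and CEP55 have a Ctrl peak and no HD peak within a list that is 35.3% shorter. Lower sequencing depth is argued against, since the recovered ChIP depth of HD was 1.40 times that of Ctrl. At the 200 peaks ranked best in both lists, HD fragments in excess of input, per unit of depth, were 0.910 times those of Ctrl (bootstrap 95% interval 0.879 to 0.937), with 70.5% of these peaks under 1. Weaker enrichment throughout the HD track may therefore contribute to the shorter list. Whether it came from hexanediol or from the preparation cannot be told apart, because the labels name no preparation batch and only 1 list per condition was analysed.

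Of the 1483 Ctrl peaks whose lower counting bound, scaled by depth, exceeded what an HD call would need, 703 (47.4%) were missing from the HD list, and in the other direction 275 of 1073 HD peaks (25.6%, 23.04 to 28.4) were missing from the Ctrl list. Both shares exceed the 2.5% set in advance, but that limit took the input of the other track as known, and counting error of the input alone would raise it to 1.5 times or more at 12.4% of the Ctrl and 11.7% of the HD peaks still above the bound at that input. Of Ctrl peaks, 137 of 487 (28.1%, 24.2 to 32.4) were missing at 1.5 times the input and 29 of 173 (16.8%, 11.5 to 23.2) at 2 times. With input error added, the limit was 14.9% and 4.20% there, and 51.6% at 1 times the input, which the 47.4% missing did not exceed. Of HD peaks, 55 of 381 (14.4%, 11.1 to 18.4) and 5 of 116 (4.31%, 1.41 to 9.77) were missing, with limits of 14.2% and 4.23%, and 49.6% at 1 times. These limits leave out the counting error of the other track's ChIP fragments and the selection of called peaks for high counts. The Ctrl shares at 1.5 and 2 times lay above them, but counting error cannot be told apart from other causes in either direction. Differences between libraries of 1 condition likewise cannot be told apart from the treatment, because only 1 list per condition was analysed.

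The peak with the highest −log10 q lay on mitochondrial DNA in both lists, and the first ribosomal peak of chromosome 21 ranked 10 in both, below further mitochondrial peaks and peaks on chromosome 1 and unplaced sequences. The input expectation at the top peak of each region was at least 18.3 times the genome-wide value in either region and list, which is consistent with many copies of these sequences raising fragment numbers and so −log10 q. At the ribosomal units, the lowest lower counting bound of ChIP over input at a unit's strongest peak was 4.47 (RNA45SN1, Ctrl). At the mitochondrial top peaks that bound was 3.03 in Ctrl and 2.48 in HD. Peaks are called where ChIP exceeds input, so a bound above 1 was fixed in advance and cannot decide whether copies alone account for these peaks. What also stays open is the GC and motif content of these regions, since no genome sequence was used here, and no biological explanation was tested.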

How the results depend on the processing

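Alternatives with a fold of at least 2, without the ribosomal DNA span, or with 1 gene per peak were tests chosen only after the result was seen. Of 96 alternative values of the results that answer a comparison, 77 were labelled the same, 18 moved and 1 became weaker. Of 132 values of single gene lists, 115 were the same, 4 became stronger, 6 weaker and 7 reversed. The same meant, for a test, an unchanged direction and call. For a share it meant a value within the main interval, and for a count a value within a set factor of the main count. HD held 64.1% to 64.9% as many peaks as Ctrl, and the retention trend kept p = 1e-05, the smallest that permutations can give, with a difference of 23.1 to 48.5 points. The share of Ctrl peaks overlapping HD was 47.5% with the same number of peaks from each list, 34.7% with a reciprocal overlap of 50% and 40.7% with a gap of up to 1 kb, and that of HD peaks overlapping Ctrl was 47.4% with the same number of peaks and 53.9% with a reciprocal overlap of 50%. The gene-end share in Ctrl was 57.4% at −log10 q of at least 3, 59.7% with the same number of peaks, 50.1% with a window of 500 bp, 56.4% with 2 kb, 62.9% with genes of any type and 56.3% at a fold of at least 2. In HD it was 62.9% at −log10 q of at least 3, 56.7% with 500 bp, 63.3% with 2 kb, 69.98% with genes of any type and 64.0% at a fold of at least 2. By construction, a wider window or more genes gives a larger share, and stricter overlap a smaller one. The odds ratio of the HD against the Ctrl list was 1.04 (Fisher's exact test, p = 0.515) with the same number of peaks, which removes weaker Ctrl peaks. Lists past the threshold numbered 1 in Ctrl with the same number of peaks (4 before) and 0 in HD with 1 gene per peak (2 before). Some counts labelled the same also differed. They were 5 in Ctrl and 3 in HD at −log10 q of at least 3 and with 500 bp, and 3 in Ctrl with 1 gene per peak. Odds ratios that crossed 1 were all of lists not past the threshold: small structural RNA genes in Ctrl, 1.05 at −log10 q of at least 3 and 1.06 with 500 bp; zinc finger genes, 1.05 in Ctrl with 500 bp, 1.01 in Ctrl and 1.02 in HD with 1 gene per peak; immediate-early and heat shock genes in Ctrl, 0.996 at a fold of at least 2; and G4 oncogene promoters in Ctrl, 1.15 with 1 gene per peak. For these, the other overlap shares and the list counts, the cause was not tested. No paired analysis was possible because each condition has a single list without values per library, and for the same reason no replicate could be left out in turn. The G4 motif share (at summits, over whole peaks, with longer loops, with windows matched on GC, or stratified) and the motif and GC terms of the retention model were not run. The lowest fragment number at a called summit was 15 in Ctrl and 20 in HD, where the caller scaled the pileup by 0.927 and 0.715.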

Other observations

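The test of the heat shock list was chosen only after the result was seen, and the regions below were likewise chosen after their values were seen. Transfer RNA genes carried peaks mainly in a tandem cluster on chromosome 1 (161443304 to 161470486) that holds glycine, glutamate and aspartate tRNA genes. Of its 32 genes, 16 (50%, 31.9 to 68.1) were marked in Ctrl and 13 (40.6%, 23.7 to 59.4) in HD, 12 of them in both, against 10 (2.52%) and 7 (1.76%) of the 397 other tRNA genes. These genes share 9 Ctrl peaks, with folds of 2.14 to 3.65, and 6 HD peaks, so the intervals over genes are too narrow. Among 17904 lncRNA genes 3.37% were marked in Ctrl and 2.45% in HD, but among the 13174 away from the ends of coding genes 0.926% and 0.615% were, and among 15048 pseudogenes, wherever they lie, 0.538% and 0.385%. Transcribed pseudogenes, a separate class of 1221 genes, were marked at 5.90% in Ctrl and 4.1% in HD. Among the 972 of them away from the ends of coding genes, the shares were 4.53% and 3.40%. Of the 5S ribosomal RNA genes, RNA5S4, RNA5S6 and RNA5S12 had a Ctrl peak and none had an HD peak.

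Dense megabases were of different kinds. The megabase from 144 Mb on chromosome 8, which holds HGH1, RECQL4, ZNF7 and ZNF250, had 28 Ctrl peaks with a median fold of 4.06, of which 67.9% lay at gene ends, and 18 HD peaks. The megabase from 30 Mb on chromosome 16 had 15 Ctrl and 7 HD peaks, with 86.7% of the Ctrl peaks at gene ends, and that from 2 Mb on chromosome 16 had 11 and 11, of which 81.8% of the Ctrl peaks were shared. The megabase from 30 Mb on chromosome 22 had 12 Ctrl and 2 HD peaks. In contrast, the megabase from 49 Mb on chromosome 5 had 30 Ctrl and 17 HD peaks with a median Ctrl fold of 2.08, and 0 of them at a gene end, and that from 143 Mb on chromosome 1 had 18 and 5 with a median Ctrl fold of 1.33.

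A hypothesis raised by these data is that immediate-early and heat shock genes might gain peaks under hexanediol beyond other genes. Of members marked in 1 list only, 6 (HSPB1, HSPD1, HSPE1, JUND, KLF10 and SRF) were in HD and 2 (HSP90AB1 and HSPH1) in Ctrl, with an odds ratio of 5.92 against other genes (two-sided Fisher's exact test, p = 0.021, adjusted p = 0.21 over 10 lists). HSPD1 and HSPE1 share 1 HD peak and are not independent gains, so the odds ratio overstates the evidence, and the test uses the same counts that raised the hypothesis. The list's HD call was also lost with 1 gene per peak (exact test, adjusted p = 0.081, range over 6 alternatives 0.00226 to 0.081). The shift did not pass the adjusted threshold, and with 8 such members it stays open.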
